A study of Homo sapiens with 6 samples.

How the data were processed

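Total RNA was extracted from HEK293T cells with an RNeasy kit and libraries were made at BGI, per the labels' protocols. Cells were transfected with Lipofectamine 2000, per the labels' protocols. The labels call the control non-transfected, while the growth protocol speaks of an empty vector. The control is called non-transfected here, as in the sample labels and the series design. The 6 samples, with 1 library per group, were grouped by the genotype in the labels.

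The authors deposited a table of estimated (expected) counts per gene symbol for the 6 libraries. The aligner and the counting program are not given in the sources used here. The submitters' processing notes name the genome build GRCh37.p13 and DESeq without a version. No strand setting is stated, so it is unknown whether reads of overlapping genes on opposite strands were told apart. Between 3.46% and 3.55% of the table's rows were fractional in a library, and genes without reads held a placeholder of 0.028, which was set to 0. The deposited expected counts were then rounded to whole numbers. Of 38072 rows, 28 had a gene name turned into a calendar date and were left out. They held between 0.215% and 0.231% of the counts. Rows that share a symbol (94 rows, 43 symbols) were summed, which left 37993 symbols. A second count table was not used. Its 6 columns of per-sample values went unused because 1 of them carries a number that matches no sample label.

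The authors also deposited comparison sheets with a fold (ratio of scaled counts), a log2 fold change and an adjusted p-value per gene, made with DESeq per the submitters' processing notes and the file headers. A few of those values were copied and are named as the authors' deposited table wherever they appear. With 1 library per side, those p-values rest on an assumed spread and not on replicates.

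Library totals were 16257520 for non-transfected, 16023952 for WT, 16089653 for M67V, 16813355 for N267star, 16752203 for ex2-3del and 16807072 for ex8-14del. At this depth the floor of 3 counts corresponds to between 0.178 and 0.187 CPM, and the 10 most abundant genes held between 2.49% and 2.70% of the counts. Effective library sizes came from TMM factors (edgeR 4.0.16 in R 4.3.3), which lay between 0.985 and 1.01. Log2 ratios of CPM used a prior count of 2. Their 95% intervals were exact conditional binomial (Clopper-Pearson) intervals of the 2 counts. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

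For each pair of libraries the number of genes with an absolute log2 ratio of at least 1, at least 5 CPM in either library and an interval that excludes 0 was counted. With 1 library per group this is a criterion of size, not a test of conditions, and no p-value was computed. Where a gene has no count in a library, a fold is given only as a bound against the floor of 3 counts. For each of 22 gene lists fixed before the data were examined, members with at least 1 CPM in either library entered. The list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and members at 1.5-fold with an interval on the same side were counted. Correlations and covariances of log2 ratios between alleles were taken across genes without ATF6 and set beside 50 simulated sets of unchanged libraries, because the alleles share 1 control library.

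Which genes the text names was set before the data were examined. The rule took ATF6, HSPA5, HSP90B1, HERPUD1, SEL1L, DDIT3 and XBP1, up to 4 members per list with the largest absolute ratio, the 10 highest and 10 lowest ratios of each allele against non-transfected cells, and the 5 highest and 5 lowest of each mutant against WT. Some members that pass a list's criterion, and genes in sets of 6 or fewer that remained after overlapping genes were set aside, are named in addition, chosen after their values were seen. The reference annotation at hand is of GRCh38, a different build from the authors' one. No coordinates are therefore given, and the annotation served only to tell which genes overlap or neighbour each other. It held 99.3% of the 11413 genes with at least 5 CPM in any library, and 20.6% of them overlap another expressed gene. The counts of such genes, and of near-identical copies, are uncertain.

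The steps were tested on simulated data for the comparison of WT with non-transfected cells, with counts drawn from the real means and library sizes and 200 genes changed in each of 20 draws. Of 11277 genes tested, 0.05 unchanged genes per draw met the 2-fold criterion. Of genes changed 1.5-fold, 0% met it, and of those changed 3-fold, 4-fold and 8-fold, 100% did. The changed genes all had at least 5 CPM in the non-transfected library, and no fold close to 2 was tried. These shares therefore do not cover genes close to silent there or changes near the criterion. The intervals covered the true ratio for 95.3% of the genes. These simulations hold counting error and no difference between cultures.

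The alternatives tried were DESeq2 1.42.0 size factors, scaling by total count, minimums of 1 and 20 CPM, a prior count of 0.5, ATF6 left out of the scaling and the counts, list members with at least 5 CPM, WT as the control of the lists, and another reference for the correlations. Leaving out genes that overlap another expressed gene was added after the data had been seen.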

Results

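The transcriptomes of HEK293T cells, a human embryonic kidney line that is easily transfected, were measured by sequencing libraries made from RNA of 6 cultures. ATF6 is an endoplasmic reticulum (ER) membrane transcription factor of the unfolded protein response, and loss-of-function alleles of its gene are linked to achromatopsia, an inherited loss of cone vision. A non-transfected culture was compared with 5 cultures that overexpressed ATF6 labelled wild type (WT) or 1 of 4 mutant alleles. These were the missense allele M67V, the nonsense allele N267star, and the multiexon deletion alleles ex2-3del and ex8-14del. Each group held 1 library, so no difference below has a replicate check, and no test between conditions could be made. The libraries held between 16023952 and 16813355 counts. Intervals in brackets are exact 95% intervals of the ratio of 2 counts, and they cover counting error only. They say how far 2 libraries differ, not how far 2 conditions do. A gene met the 2-fold criterion when the libraries differed by at least 2-fold, the interval excluded equality and either library held at least 5 CPM, the customary count unit scaled to library size.

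ATF6 itself was higher in all 5 transfected libraries. Its level was 85.1 CPM in the non-transfected library, 1148 CPM in WT, 1493 CPM in M67V, 713 CPM in N267star, 1349 CPM in ex2-3del and 2410 CPM in ex8-14del. The log2 ratios to the non-transfected library were 3.75 (3.67 to 3.83) for WT, 4.13 (4.05 to 4.21) for M67V, 3.06 (2.99 to 3.15) for N267star, 3.98 (3.91 to 4.07) for ex2-3del and 4.82 (4.75 to 4.90) for ex8-14del. Reads of the endogenous gene and of the introduced allele were counted together, and a deletion shortens the transcript that can give reads. The levels therefore show that the total ATF6 count was higher with each allele. They do not separate the introduced allele from the endogenous gene, and they do not rank the amounts of transcript. The ATF6 count level and the level of the target gene HSPA5 did not run in parallel. The ex8-14del library had 2.10 times the ATF6 count level of WT, while HSPA5 stood at 741 CPM in ex8-14del against 3634 CPM in WT.

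**Figure D1:**
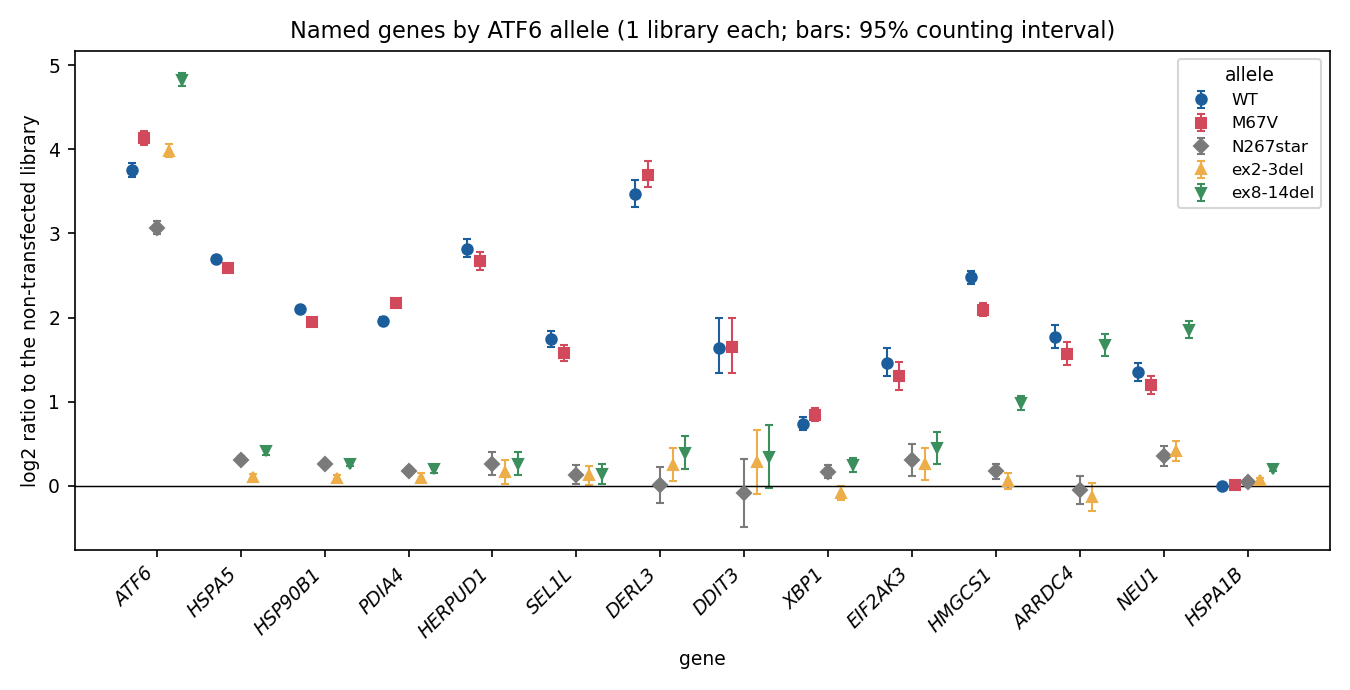
Log2 ratios of 14 named genes to the non-transfected library (vertical axis) for the 5 ATF6 alleles, 1 library each, with exact 95% counting intervals as bars. HSPA5 stood at 2.70 in WT and 2.59 in M67V, and at 0.31, 0.10 and 0.41 in N267star, ex2-3del and ex8-14del.

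The comparison of WT with non-transfected cells asked what overexpression of the ATF6 labelled WT does to the transcriptome. Whether that construct was full length is not stated in the sources used here, as set out with the authors' deposited values below. Many genes of ER protein folding, and some of ER-associated degradation, were higher than in non-transfected cells. HSPA5, the ER chaperone BiP, was 6.50-fold higher (log2 ratio 2.70, 2.67 to 2.73), from 559 to 3634 CPM. HSP90B1, the ER chaperone GRP94, was 4.30-fold higher (2.10, 2.07 to 2.13), and the disulfide isomerases PDIA4 and P4HB were 3.89-fold and 2.94-fold higher. Of the 31 measured members of the ER chaperone and folding enzyme list, 17 were at least 1.5-fold higher with an interval above equality. No member was lower by as much. The list median was a log2 ratio of 0.71, above the medians of all 10000 random lists matched on expression. CRELD1 (1.75, 1.61 to 1.91) and MANF (1.65, 1.57 to 1.72) were also among the 17 genes.

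Among 25 genes of ER-associated degradation, 5 were at least 1.5-fold higher in WT and the median was 0.27. HERPUD1, an ER membrane protein that assists degradation, was 7.07-fold higher (2.82, 2.71 to 2.93). SEL1L, the adaptor of the HRD1 ubiquitin ligase, was 3.35-fold higher (1.74, 1.65 to 1.84). DERL3, a derlin, went from 22.7 to 252 CPM (3.46, 3.32 to 3.63), although it overlaps the expressed gene SMARCB1 and its count is uncertain for that reason. EIF2AK3, which encodes the ER stress sensor PERK, was 2.77-fold higher. XBP1, the transcription factor that IRE1 activates by splicing, was 1.67-fold higher (0.74, 0.66 to 0.81), and it was the only 1 of 30 XBP1-linked secretory genes at 1.5-fold. Of 36 measured genes of the PERK and ATF4 pathway and amino acid response, 3 were at least 1.5-fold higher, with a list median of 0.17. They were DDIT3 (1.64, 1.34 to 1.99), which encodes the transcription factor CHOP and overlaps the expressed gene MARS, ADM2 and CTH. Of 23 cholesterol synthesis genes, 4 were at least 1.5-fold higher, with a median of 0.17. HMGCS1, the enzyme that makes HMG-CoA, was 5.57-fold higher (2.48, 2.40 to 2.55), IDI1 was 2.62-fold higher and overlaps the expressed gene WDR37, and STARD4 and NSDHL stood at 0.95 and 0.83.

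Over 11301 genes tested, 82 were at least 2-fold higher and 7 at least 2-fold lower in WT than in the non-transfected library, and the median log2 ratio of all of them was -0.007. Several of the highest ratios belonged to genes close to silent in non-transfected cells. The diacylglycerol kinase gene DGKK, the homeobox gene DLX3, the glutamate receptor gene GRM8, TLL2 and C7orf57 stood at 0.061, 1.10, 0.183, 1.65 and 0.549 CPM there, and at 7.99, 19.6, 6.23, 16.5 and 21.5 CPM in WT. MISP had no count in the non-transfected library and 8.25 CPM in WT, which is at least 45-fold higher when the floor of 3 counts is used. Genes that overlap another expressed gene were 32.6% of those at 2-fold against 20.6% of the genes tested, and without them 58 genes were higher and 2 lower. The 2 lower genes were FAXDC2, at 19.4 CPM in the non-transfected library and 1.76 CPM in WT, and TTLL1 (-1.08, -1.72 to -0.55).

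The M67V allele was compared with non-transfected cells and with WT to ask what the missense change does to this response. HSPA5 was 6.04-fold higher than in non-transfected cells (2.59, 2.56 to 2.63), HSP90B1 3.85-fold, HERPUD1 6.38-fold and PDIA4 4.51-fold. Of the 31 chaperones and folding enzymes, 16 were at least 1.5-fold higher, with a median of 0.77, and 6 of the 25 degradation genes were, with a median of 0.28. HMGCS1 was 4.27-fold higher, and 5 of 23 cholesterol synthesis genes reached 1.5-fold, with a median of 0.22. DDIT3 stood at 1.65 (1.34 to 1.99). In all, 82 genes were at least 2-fold higher and 9 lower of 11304 tested. Without the genes that overlap another expressed gene, 58 were higher and 1 lower. This was C9orf24, at 47.1 CPM in non-transfected cells and 4.48 CPM in M67V. Among the highest ratios, CHMP3, a subunit of the ESCRT-III complex, stood at 4.20 (3.87 to 4.65). RNF103-CHMP3, which overlaps it, stood at -1.99 (-2.17 to -1.83). Scaled to the depth of the non-transfected library, CHMP3 gained 1059 reads in M67V and RNF103-CHMP3 lost 1083. Reads assigned to one or the other of these overlapping genes can therefore account for both ratios.

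Set directly against WT, M67V showed small differences in these genes, some of them beyond counting error. HSPA5 was 0.929 times the WT level (log2 ratio -0.11, -0.12 to -0.09), HSP90B1 0.895 times, HMGCS1 0.766 times and PDIA4 1.16 times. The median of the chaperone list was 0.01, within the range of random lists. Of 11301 genes, 7 were at least 2-fold higher and 8 lower than in WT. Apart from genes that overlap another expressed gene these were FAXDC2 and FAM219A, which were higher, and C9orf24, which was lower. C9orf24 and FAM219A are neighbouring genes. Against non-transfected cells and scaled to the depth of that library, FAM219A gained 742 reads in M67V and C9orf24 lost 699. Of the genes tested in both comparisons with non-transfected cells, 77 were at least 2-fold higher in WT, 77 were in M67V, and 72 were in both, where independent lists of these sizes would share 0.53. Both comparisons use the same control library, and part of this excess can come from it. With ATF6 set aside, 71 genes were higher in both, and 19 of them belonged to the gene lists fixed beforehand.

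**Figure D2:**
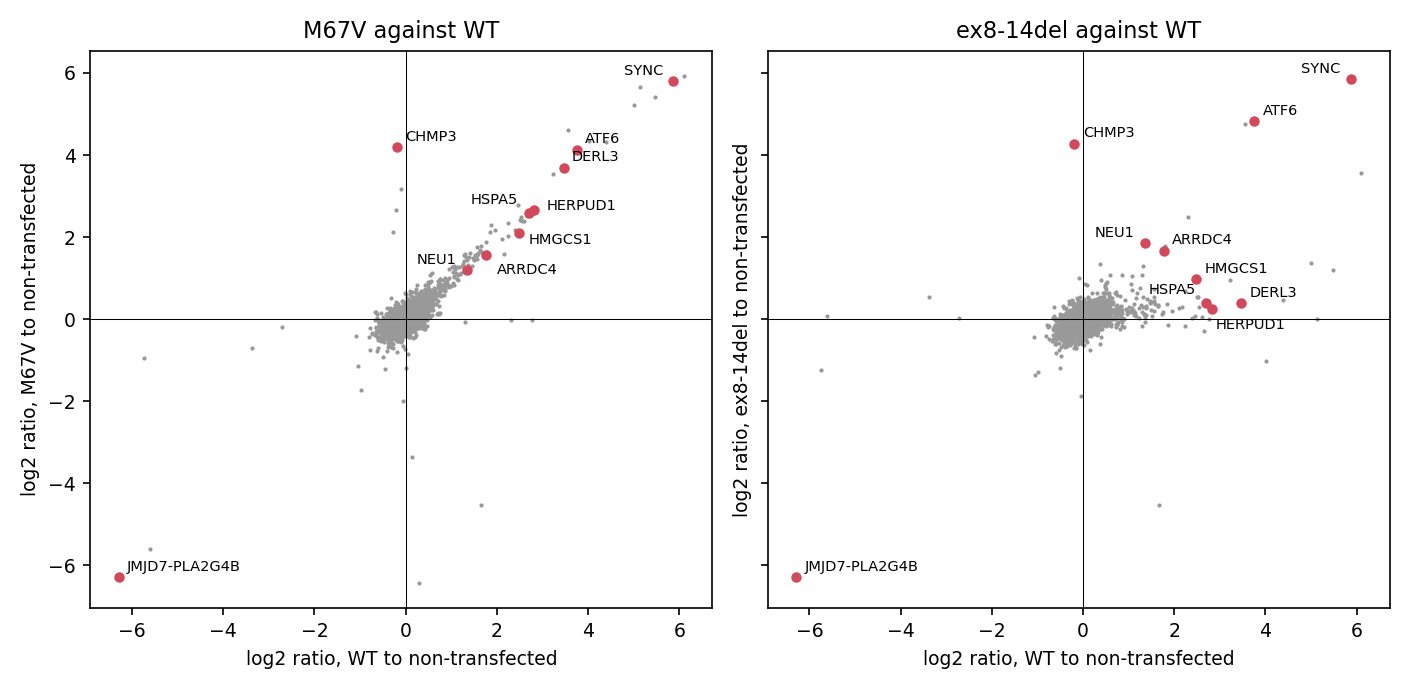
Log2 ratios to the non-transfected library of genes with at least 5 CPM in any library, for M67V (left) and ex8-14del (right) on the vertical axis against WT on the horizontal axis, where points of genes with no count in a library, such as JMJD7-PLA2G4B, depend on the prior count of 2. HSPA5 lies near the diagonal for M67V (2.59 against 2.70) and near 0 for ex8-14del (0.41), while ARRDC4 and NEU1 are high in both panels.

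The nonsense allele N267star differed from non-transfected cells in few genes. HSPA5 was 1.24-fold higher (0.31, 0.27 to 0.35), HSP90B1 1.20-fold (0.26, 0.22 to 0.29) and HERPUD1 1.20-fold (0.26, 0.13 to 0.40). DDIT3 (-0.09, -0.49 to 0.32) and DERL3 (0.01, -0.20 to 0.22) did not differ beyond counting error. Of the 31 chaperones and folding enzymes 0 reached 1.5-fold, although 30 had a ratio above 0 and the median of 0.16 exceeded that of every random list. No degradation, cholesterol synthesis or PERK pathway gene reached 1.5-fold, with medians of 0.10, 0.05 and 0.04. Of 11263 genes, 6 were at least 2-fold higher and 5 lower, and 9 of these 11 overlap another expressed gene. The others were ATF6 and FAXDC2, which was at 2.25 CPM.

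In cells with ex2-3del, HSPA5 was 1.07-fold higher than in non-transfected cells (0.10, 0.06 to 0.14), HSP90B1 1.07-fold (0.09, 0.06 to 0.13) and HERPUD1 1.12-fold (0.16, 0.03 to 0.30). XBP1 stood at -0.08 (-0.17 to 0.00). Of the 31 chaperones and folding enzymes 0 reached 1.5-fold, and the median was 0.10. No degradation or cholesterol synthesis gene did either, with medians of 0.09 and 0.05, and in the PERK pathway list ATF3 alone did (0.63, 0.44 to 0.84). Of 11279 genes, 8 were at least 2-fold higher and 4 lower, and 8 of these 12 overlap another expressed gene. The remaining 4 were ATF6, FAM174B (1.64, 1.21 to 2.15), FAM219A (1.46, 1.25 to 1.70) and C9orf24 (-1.11, -1.30 to -0.93). FAM219A gained 391 reads, scaled as above, and C9orf24 lost 415.

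The ex8-14del library had the highest ATF6 count and a partly different profile. HSPA5 was 1.33-fold higher than in non-transfected cells (0.41, 0.37 to 0.45), P4HB 1.45-fold (0.54, 0.50 to 0.58) and HERPUD1 1.20-fold (0.26, 0.12 to 0.40). Of the 31 chaperones and folding enzymes 0 reached 1.5-fold, with a median of 0.16, and 0 of the 25 degradation genes did, with a median of 0.05. HMGCS1 was 1.98-fold higher (0.99, 0.90 to 1.07) and was the single cholesterol synthesis gene at 1.5-fold; that list had a median of 0.15. A few genes outside the ER lists reached WT-like levels. NEU1, the lysosomal sialidase, was 3.63-fold higher (1.86, 1.76 to 1.96), above its level in WT by 1.42 times. ARRDC4, an arrestin-domain gene, was 3.19-fold higher (1.67, 1.54 to 1.81), and MXD1, a MAX-binding repressor that overlaps the expressed gene ASPRV1, stood at 1.78 (1.62 to 1.97). ARRDC4 and MXD1 did not differ beyond counting error from non-transfected cells in N267star (-0.05 and 0.12) or in ex2-3del (-0.13 and -0.22), while NEU1 was higher in both, at 0.35 (0.23 to 0.48) and 0.41 (0.29 to 0.53). GPR50, an orphan receptor gene, was 2.55-fold higher in ex8-14del (1.34, 1.12 to 1.59). Of 11263 genes, 14 were at least 2-fold higher and 6 lower, and 14 of these 20 overlap another expressed gene. The other 6 were ATF6, NEU1, ARRDC4, GPR50, EGR1 and ARNTL.

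Against WT, some chaperone and degradation genes were lower in N267star, ex2-3del and ex8-14del. HSPA5 was 0.191 times the WT level in N267star (-2.39, -2.42 to -2.36), 0.165 times in ex2-3del (-2.60, -2.63 to -2.57) and 0.204 times in ex8-14del (-2.29, -2.32 to -2.27). HERPUD1 stood at -2.56, -2.66 and -2.56, SEL1L at -1.61, -1.62 and -1.60, and HMGCS1 at -2.31, -2.42 and -1.49. Of the chaperones and folding enzymes, 14 were at least 1.5-fold lower than WT in N267star, 14 in ex2-3del and 15 in ex8-14del, and 5 of the 25 degradation genes were in each. The chaperone list medians were -0.47, -0.46 and -0.58, each below those of all 10000 random lists. Genes at least 2-fold lower than WT numbered 75, 65 and 58, and genes at least 2-fold higher 5, 5 and 7. Among the 71 genes that were 2-fold higher in both WT and M67V, the median log2 ratio to non-transfected cells was 1.56 in WT, 1.57 in M67V, 0.12 in N267star, 0.12 in ex2-3del and 0.31 in ex8-14del. Those 71 genes were picked from the WT and M67V libraries against the same non-transfected library, so their medians in WT and M67V are no independent evidence, and 19 of the 71 overlap another expressed gene.

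**Figure D3:**
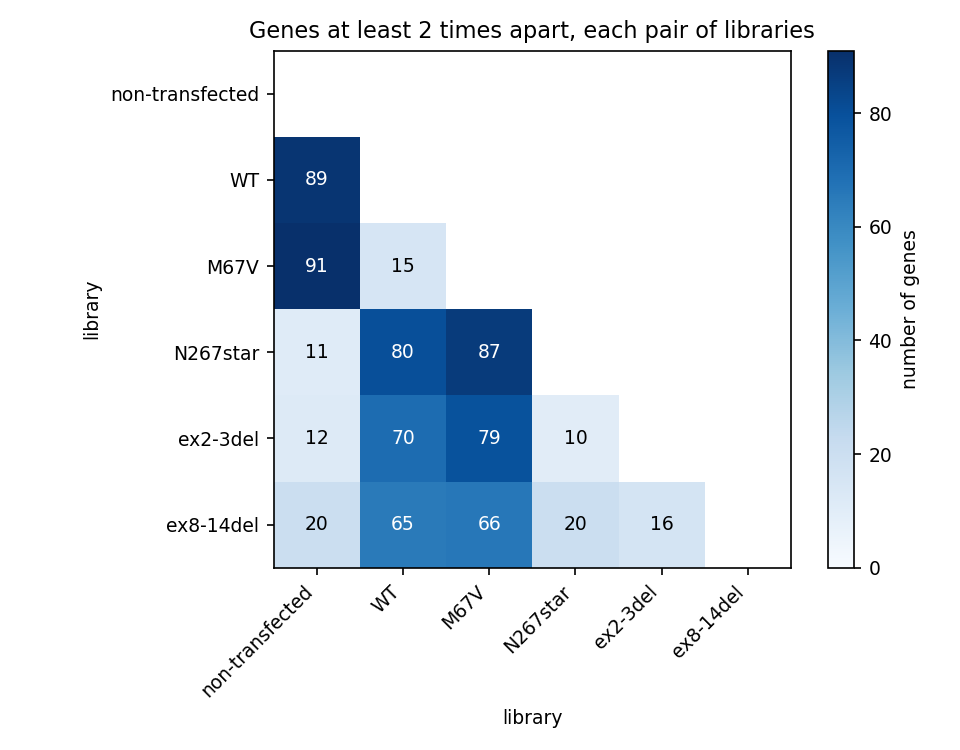
Number of genes at least 2-fold apart in each of the 15 pairs of libraries, with libraries on both axes and the colour scale giving the number of genes. WT and M67V differ in 15 genes, and each differs from the other 4 libraries in 65 to 91.

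Besides ATF6, PHKG1 and SYNC were at least 2-fold higher in all 5 transfected libraries, and JMJD7-PLA2G4B was lower in all 5. PHKG1 stood at 0.98 CPM in non-transfected cells and between 12.8 and 29.7 CPM in the others, and SYNC at 0.73 CPM and between 46.0 and 49.9 CPM. JMJD7-PLA2G4B was at 9.4 CPM in non-transfected cells and had no count in the others, which is at least 49.8-fold lower in WT with the floor of 3 counts. All 3 overlap another expressed gene, and their counts are uncertain.

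The counts of genes at least 2-fold apart, taken over all 15 pairs of libraries, showed the same arrangement. WT differed from non-transfected cells, N267star, ex2-3del and ex8-14del in 89, 80, 70 and 65 genes, and M67V in 91, 87, 79 and 66. WT and M67V differed in 15 genes. Non-transfected cells differed from N267star, ex2-3del and ex8-14del in 11, 12 and 20 genes, and these alleles differed from one another in 10, 20 and 16. Across 11412 genes, which are not independent replicates, the log2 ratios of WT and M67V to the non-transfected library had a Pearson correlation of 0.764. Unchanged libraries simulated against that same control gave 0.491. The covariance was 0.0601 against 0.0052 in the simulation. These simulated libraries hold counting error only, with no difference between cultures and no reassignment of reads between overlapping genes. For the other 9 pairs of alleles the correlation was between 0.417 and 0.640. Their covariance was between 0.0208 and 0.0310, also above the simulated value, so an excess over the simulation is not particular to WT and M67V. Over the 8984 genes that overlap no expressed gene, the correlation was 0.824 for WT and M67V and between 0.303 and 0.588 for the other 9 pairs. When WT and M67V were referred to the geometric mean of the other 4 libraries, which is again a reference that both share, the correlation was 0.659, and unchanged libraries simulated in the same way gave 0.192.

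**Figure D4:**
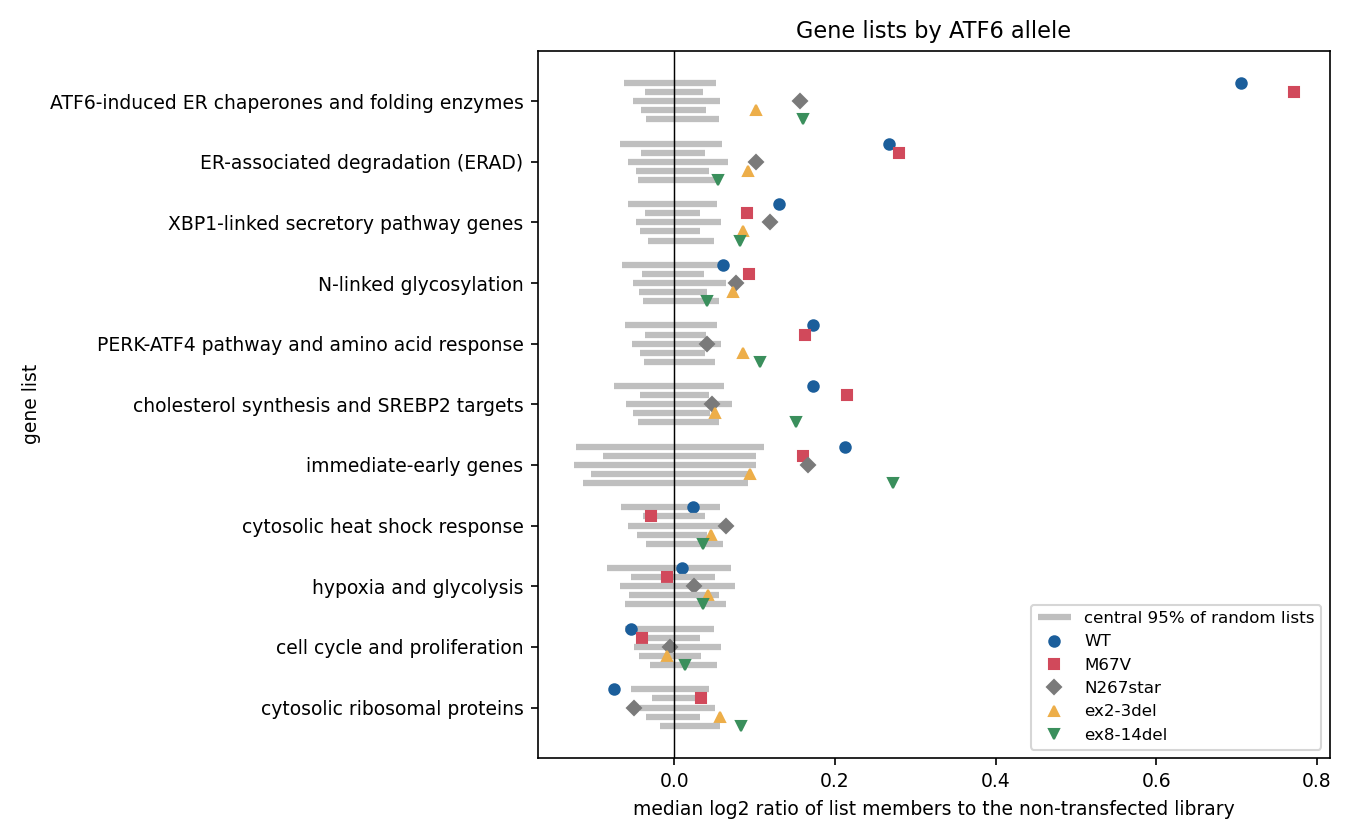
Median log2 ratio to the non-transfected library (horizontal axis) of the measured members of 11 gene lists for the 5 alleles, with grey bars for the central 95% of expression-matched random lists. The chaperone list stood at 0.71 in WT and 0.77 in M67V, and between 0.10 and 0.16 in the other alleles.

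XBP1-linked secretory genes had medians of 0.13, 0.09, 0.12, 0.09 and 0.08 in WT, M67V, N267star, ex2-3del and ex8-14del, each above those of all 10000 random lists. N-linked glycosylation genes had medians of 0.06, 0.09, 0.08, 0.07 and 0.04, with GMPPB in M67V, which overlaps the expressed gene RNF123, as the single glycosylation gene at 1.5-fold. The cytosolic heat shock list stood at 0.02, -0.03, 0.06, 0.05 and 0.04 and no member reached 1.5-fold. Medians of fatty acid synthesis genes were 0.03, 0.03, 0.06, 0.02 and 0.02, those of hypoxia and glycolysis genes were 0.01, -0.01, 0.03, 0.04 and 0.04, and no member of either list reached 1.5-fold. Interferon response genes had medians of 0.01, -0.001, -0.09, 0.02 and -0.09. At 1.28 and 1.77 CPM in non-transfected cells, ISG15 was higher in M67V (0.88, 0.14 to 1.78) and N267star (0.93, 0.20 to 1.82), and IFIH1 was lower in ex2-3del (-0.91, on 15 counts against 29). The p53 list had medians of -0.05, -0.06, 0.07, 0.07 and 0.07, with GADD45B (0.74, 0.66) the highest member in WT and M67V and GADD45A (0.59) at 1.5-fold in WT. Cell cycle genes stood at -0.05, -0.04, -0.01, -0.01 and 0.01. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, was the exception among them, at 1.94-fold in WT (0.96, 0.89 to 1.03) and 2.02-fold in M67V. Cytosolic ribosomal protein genes had medians of -0.08, 0.03, -0.05, 0.06 and 0.08, and 28 of 28 members were above 0 in ex8-14del. These small shifts lay at or beyond the edge of the random lists too, at percentiles of 0.29, 98.7, 1.37, 99.97 and 99.98.

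Immediate-early genes had medians of 0.21, 0.16, 0.17, 0.09 and 0.27 in WT, M67V, N267star, ex2-3del and ex8-14del. In the same order these lay at percentiles of 99.96, 99.85, 99.93, 97.43 and 100 among random lists, all against the same control library. Of 18 measured, those at 1.5-fold were FOS (1.74) and EGR1 (0.59) in WT, FOS (1.59) and ATF3 (0.72) in M67V, ATF3 (0.63) in ex2-3del, and FOS (1.27), EGR1 (1.09), KLF6 (0.65) and ATF3 (0.64) in ex8-14del. FOS was at 0.671 CPM and EGR1 at 3.60 CPM in non-transfected cells. ATF3, a stress-induced transcription factor, was 1.41-fold to 1.65-fold higher in all 5 transfected libraries. The ATF and CREB family list had medians of 0.06, 0.08, 0.05, -0.02 and 0.05, and ER stress sensors and site proteases -0.01, 0.06, 0.03, 0.01 and 0.04. Replication-dependent histone genes had medians of 0.09, 0.06, -0.08, -0.08 and 0.16 over 10 or 11 measured members, whose reads can be split between near-identical copies. Their members at 1.5-fold were HIST1H3D and HIST2H2BE in WT, HIST2H2BE and HIST2H2AC in M67V, HIST2H2BE in ex8-14del, and HIST1H1E in N267star (1.40, 0.22 to 3.51), on 17 counts against 5. Of 15 achromatopsia genes and cone markers, 3 or 4 reached 1 CPM, ATF6 among them. Their medians were 1.10, 0.40, 0.13, 1.17 and 0.94. The cone opsin gene OPN1SW, which overlaps the expressed gene CALU, was at 0.305 CPM in non-transfected cells and at 1.45, 0.379, 0.237, 2.07 and 1.43 CPM in WT, M67V, N267star, ex2-3del and ex8-14del. Markers of other cell types were few. Fibroblast markers, with 4 or 5 measured, had medians of 0.08, 0.31, -0.10, -0.12 and -0.06, keratin epithelial markers, with 4 measured, had 0.14, 0.18, -0.13, 0.17 and -0.06, and blood cell markers, with 3 measured, had -0.47, -0.18, -0.62, -0.63 and -0.20. No symbol of the 15 listed mitochondrially encoded genes was matched among the deposited counts, so that list has no median.

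The authors' deposited table gives DESeq comparisons of each transfected library with the non-transfected one, made from 1 library per side. In the authors' deposited table HSPA5 is 6.51-fold higher in the comparison that corresponds to WT, 6.03-fold in M67V, 1.24-fold in N267star, 1.08-fold in ex2-3del and 1.33-fold in ex8-14del. At an adjusted p under 0.05 and at least 2-fold, the authors' deposited table holds 88 genes higher and 8 lower for WT, 90 and 10 for M67V, 8 and 6 for N267star, 13 and 7 for ex2-3del, and 17 and 9 for ex8-14del. In one of the authors' deposited sheets the WT comparison carries a number as its name, while another sheet calls the same values WT. All 15473 of their log2 fold changes compared were equal within 1e-06. The number equals the last residue of a cytosolic ATF6 fragment that is widely used as a constitutively active form. The labels name the sample WT, and the sources used here do not say whether that construct was full length, so every comparison with WT carries this uncertainty.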

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

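1 signal stood in data that no comparison above uses. It is in a table entry whose gene name had been turned into a calendar date, so that it names no gene here. The entry was at 18.2 CPM in the non-transfected library, 34.7 CPM in WT, 45.4 CPM in M67V, 14.2 CPM in N267star, 20.2 CPM in ex2-3del and 16.9 CPM in ex8-14del. Its log2 ratio of M67V to non-transfected was 1.31 (95% counting interval 1.12 to 1.52), which meets the 2-fold criterion. No explanation, technical or biological, was tested for it. No gene was at least 2-fold higher in 1 allele and at least 2-fold lower in another against non-transfected cells.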

How the results depend on the processing

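The alternatives were planned, except for leaving out overlapping genes, which was chosen after the data had been seen. DESeq2 size factors, total-count scaling, a prior count of 0.5 and ATF6 left out kept all 9 counts of genes at 2-fold within 1.5 times, and the ATF6 ratios stayed within their counting intervals in all 15 values recomputed. With a minimum of 1 CPM, which tests more genes of low count, the counts against non-transfected cells were 170 for WT, 159 for M67V, 61 for N267star, 63 for ex2-3del and 73 for ex8-14del, and against WT 68 for M67V, 159 for N267star, 139 for ex2-3del and 148 for ex8-14del. With 20 CPM, which tests fewer, they were 49 for WT, 58 for M67V, 4 for N267star and 6 for ex2-3del, and against WT 7, 47, 45 and 37 in the order M67V, N267star, ex2-3del, ex8-14del. Without overlapping genes, which again tests fewer, M67V kept 59 calls, N267star 2, ex2-3del 4 and ex8-14del 6 against non-transfected cells, and M67V 3 against WT. Against the geometric mean of the libraries outside the pair, which puts another shared reference in place of the shared control, unchanged libraries gave a simulated correlation between 0.192 and 0.210. The observed correlation was 0.659 for WT with M67V, 0.153 for WT with N267star, -0.145 for WT with ex2-3del, -0.054 for WT with ex8-14del, -0.178 for M67V with N267star, -0.038 for M67V with ex2-3del, 0.127 for M67V with ex8-14del, 0.511 for N267star with ex2-3del, 0.283 for N267star with ex8-14del and 0.427 for ex2-3del with ex8-14del. The changes of sign carry no information on these pairs, since the reference of a pair with WT holds the similar M67V library, and that of a pair with M67V holds WT. For pairs among N267star, ex2-3del and ex8-14del the reference holds both WT and M67V. The change of WT and M67V then enters both sides of the pair and can raise its correlation, which the simulated values do not include. With WT in place of the non-transfected library as the control, which subtracts the change of WT itself, the chaperone list stood at 0.01 in M67V, -0.467 in N267star, -0.455 in ex2-3del and -0.577 in ex8-14del. Under that control, by the same subtraction, other list medians changed sign: ERAD to -0.029 (M67V), -0.161 (N267star) and -0.192 (ex2-3del), XBP1-linked genes to -0.027, -0.018, -0.055 and -0.089 (M67V, N267star, ex2-3del, ex8-14del), cell cycle to 0.038 (M67V), immediate-early to -0.101 (N267star), ribosomal proteins to 0.024 (N267star), N-linked glycosylation to -0.018 (ex2-3del), the PERK and ATF4 list to -0.02 (ex2-3del) and -0.014 (ex8-14del), cholesterol synthesis to -0.087 (ex2-3del) and -0.039 (ex8-14del), achromatopsia genes to -0.04 (ex2-3del) and -0.15 (ex8-14del) and histones to -0.109 (ex8-14del). With members of at least 5 CPM the fibroblast median in M67V was -0.002, over 3 genes instead of 5. Over all alternatives, 459 list medians moved by less than the typical counting error of a member, 22 that had stood apart from random lists changed sign, and 11 moved by more, a few of these across 0. Alternatives planned for several columns per sample (a DESeq2 test, leaving out columns, a replicate block) were not run, since each sample has 1 column. No paired analysis was possible because each group holds 1 library, numbered 1. Depth does not limit the ratio of an abundant gene such as HSPA5, which rests on 9157 counts in the non-transfected library and 57731 in WT, but it limits those of genes close to silent there, such as DGKK in WT (5.47, 4.53 to 12.35). Also missing is a measure of the spread between cultures, and genes near 1 CPM rest on fewer than 20 counts.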

Other observations

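The tests on the patterns weighed here were chosen after the results were seen, and the chaperone list was set against the middle of the unrelated lists only after it had been set against the farthest of them. Of the 71 genes other than ATF6 that were 2-fold higher in both WT and M67V, 19 belong to the lists fixed beforehand, and the rest to none of them. The following were chosen after their values were seen, among those that overlap no expressed gene. TSPYL2 stood at 112 CPM in non-transfected cells and at 331 and 310 CPM in WT and M67V, and the circadian repressor gene PER1 at 109, 285 and 311 CPM. CDK2AP2 went from 62.1 to 178 and 183 CPM, and the neuronal tubulin gene TUBB3 from 30.5 to 78.9 and 76.2 CPM. CORO1A, which encodes the actin-binding protein coronin 1A, was at 4.82 CPM against 26.9 and 33.8 CPM, and ZNF804A at 4.03 against 26.0 and 23.7 CPM. In N267star and ex2-3del the log2 ratios of these 6 genes lay between -0.22 and 0.29, and in ex8-14del TSPYL2 stood at 0.74 (0.65 to 0.82), CDK2AP2 at 0.41 (0.29 to 0.53), PER1 at 0.31 (0.22 to 0.40), TUBB3 at 0.30 (0.13 to 0.47), CORO1A at 0.07 (-0.39 to 0.53) and ZNF804A at -0.29 (-0.84 to 0.24).

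The ex8-14del library shared a small part of that set. Of the 71 genes, 52 overlap no expressed gene, and of these 9 (17.3%) were at least 1.5-fold higher in ex8-14del, 1 (1.9%) in N267star and 3 (5.8%) in ex2-3del, and in the same order 88.5%, 76.9% and 73.1% were above the non-transfected level. Some of these genes were below 5 CPM both in the non-transfected library and in that of the allele. In ex8-14del they were MISP (1.31 CPM), C7orf57 (1.61 CPM), TLL2 (3.33 CPM) and NEK10 (4.82 CPM). Among the 3 in ex2-3del they were DLX3 (2.13 CPM) and TLL2 (2.78 CPM). The genes had been picked against that same library. The same selection in 50 sets simulated with no change of the allele, which hold counting error only and were made after the counts were seen, gave at most 4.8%, 4.2% and 4.4% at 1.5-fold and at most 68.0%, 66.7% and 73.3% above that level. In N267star the share at 1.5-fold, and in ex2-3del the share above that level, therefore lay within the simulated range. The median log2 ratios of the 52 genes were 0.139 in N267star, 0.114 in ex2-3del and 0.307 in ex8-14del. The highest simulated medians were 0.036, 0.066 and 0.029, but the simulations hold no difference between cultures. The clock gene ARNTL stood at 1.08 (0.83 to 1.36) in ex8-14del, 0.85 in WT, 0.68 in M67V, -0.13 in N267star and 0.08 in ex2-3del. FAXDC2 had an irregular course over the libraries, at 19.4, 1.76, 11.9, 2.25, 30.4 and 28.3 CPM in non-transfected, WT, M67V, N267star, ex2-3del and ex8-14del.

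The first pattern is the genes that differed by 2-fold between non-transfected cells and the N267star, ex2-3del or ex8-14del library. Over these alleles 28 genes did, ATF6 aside, and 67.9% of them (19 genes; exact 95% interval 47.6% to 84.1%) overlap another expressed gene, against 20.6% of the genes tested. This is consistent with reads of overlapping genes being assigned to one or the other gene in different libraries. These 19 genes made 31 pairs of a gene and a library, and in 20 pairs the overlapping genes changed the opposite way by 0.5 to 1.5 reads per read, with an interval above 0, while 8 pairs were undecided and in 3 pairs (ATP6V1C2 in N267star, MPV17L2 and MXD1 in ex8-14del) the interval lay below 0.5. The pairs are not independent. CHMP3 and RNF103-CHMP3 in ex8-14del, and PLA2G4B and JMJD7-PLA2G4B in ex2-3del, are the 2 sides of 1 exchange. PHKG1, SYNC and JMJD7-PLA2G4B entered in N267star, ex2-3del and ex8-14del, each time against the same control library. The interval on the 19 of 28 genes likewise treats both sides of an exchange as separate genes. The neighbours FAM219A and C9orf24 overlap no expressed gene, but in ex2-3del C9orf24 lost 1.06 (0.89 to 1.23) reads per read that FAM219A gained, so a response to the alleles stays open, and was not tested, for the other called genes without overlap, for the 3 pairs without an exchange and for the 8 undecided ones.

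PHKG1 and SYNC were at least 2-fold higher in all 5 transfected libraries. For PHKG1, a candidate explanation is an exchange of reads with the overlapping gene SUMF2, which lost a median of 1.13 reads for each read PHKG1 gained, between 0.941 and 1.38 over the libraries. For SYNC and the overlapping gene RBBP4 the median was 0.72, but it ranged from -0.002 in WT to 1.06 in ex2-3del, so an exchange of reads was not shown for every library. A response of the cells to transfection cannot be told apart from a peculiarity of the non-transfected library, since both genes were higher in 5 of 5 transfected libraries and 1 library is labelled non-transfected. Whether that control received an empty vector, of which the growth protocol speaks, is itself not settled.

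The third pattern is a small rise of ER gene lists in N267star, ex2-3del and ex8-14del, where the chaperone medians of 0.156, 0.102 and 0.16 and the XBP1-linked medians of 0.119, 0.085 and 0.082 exceeded those of all random lists, as did the ERAD median of 0.092 in ex2-3del and the PERK and ATF4 medians of 0.085 in ex2-3del and 0.106 in ex8-14del. Exceeding the random lists was not particular to ER lists. In ex8-14del the immediate-early median of 0.272 and the cholesterol synthesis median of 0.152 exceeded all of them too. In ex2-3del the ribosomal protein median of 0.057 lay at percentile 99.97. Reads carried over from the WT library would add the same percent of the WT rise to every gene. The summed CPM of the chaperone list needs 9.01% in N267star and 10.3% in ex8-14del, while 6 genes outside the lists, without overlap, that were at least 8-fold higher in WT and M67V showed 1.56% (0.28% to 3.07%) and 4.94% (3.32% to 6.79%), which argues against carry-over as the whole cause; in ex2-3del the values were 4.96% and 3.41% (1.94% to 5.11%), which decides nothing. A shift of the whole library would move unrelated lists as far. The chaperone median exceeded the median of 10 lists outside the ER and ATF6 ones by 0.12, 0.058 and 0.106. Each difference was more than the SD of those lists (0.078, 0.049 and 0.099), by a narrow margin in ex2-3del and ex8-14del. The differences from the farthest list, the immediate-early genes, were -0.01, 0.008 and -0.112. The middle of the unrelated lists thus moved less than the chaperone list, while the farthest moved about as far or farther. Since the middle was used only after the farthest list, this comparison cannot decide on a shift. In addition, 2 of the 10 lists rose in WT itself. Immediate-early and cholesterol synthesis genes had WT medians of 0.212 and 0.172, at percentiles of 99.96 and 100 among random lists. A weak effect of the alleles could move these lists too, so their movement cannot tell such an effect from a shift. What stays open is a shift that takes in some unrelated lists (in ex8-14del histones at 0.159 and cholesterol synthesis at 0.152 lay close to the chaperone list too), and a weak effect of these alleles or of transfection, which the design with 1 library per allele does not separate and which was not tested.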
